A study of Mus musculus with 12 samples.

How the data were processed

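RNA from 6 brain regions of mice lacking interleukin-18 (IL-18, a cytokine of the interleukin-1 family; KO) and of wild-type (WT) littermates was measured on 12 one-colour arrays. Per the labels, the mice were males of 12 weeks, equal amounts of RNA from 5 mice were pooled for each array, and 400 ng of total RNA were labelled with Cy3. Each region and genotype had 1 array. The labels do not say whether the pools of different regions came from the same 5 mice. The arrays lay on 6 slides, 1 slide per region, with the WT and the KO array of a region in the same places on every slide, so position on the slide and genotype cannot be told apart.

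The spot intensity values were deposited as scanner output of Agilent Feature Extraction 9.5.3.1, per the file headers. The processed intensity used here had been background-subtracted and detrended by that software and had not been scaled between arrays, per the file headers. The authors also deposited a table of KO over WT ratio values. For probes with 1 spot, this authors' ratio equalled the ratio of processed intensities times 1 constant per region, with a largest log2 deviation of 0.0069, in the striatum. The log2 constants were -0.17, -0.13, -0.39, -0.30, -0.27 and 0.064 in olfactory bulb, prefrontal cortex, striatum, amygdala, hippocampus and hypothalamus, close to the shifts of -0.17, -0.12, -0.38, -0.30, -0.28 and 0.067 that the 75th percentile gave here. The column medians of the deposited ratio lay between 0.982 and 1.02. The ratio runs KO over WT on a linear scale; how the authors chose the constants is not given in the sources used here. A probe with 10 spots was listed once there, with a combined ratio.

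From the deposited intensity, log2 of the processed signal was taken and the 75th percentile of each array, over its 43379 gene spots, was subtracted. Control spots were left out. Spots that the scanner software marked as outliers, between 61 and 143 per array, were left out, and no spot was saturated. The spots of a probe were averaged, which concerned 245 probes with 10 spots each. The files hold no gene symbols. Their accessions were matched without versions to a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of genes along the chromosome. Of 41174 gene probes, 22951 (55.7%) matched, giving 16357 named genes among 33390 genes and unnamed transcripts. Each gene was represented by its probe with the highest mean over the 12 arrays. For the comparison across regions, 24859 genes and transcripts were kept whose probe was well above background, by the scanner software's flag, on at least 6 of the 12 arrays. For a comparison within a region the probe had to pass on both arrays.

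The KO minus WT difference across regions was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with region as a block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The repeated unit was the region. Because the pools of different regions can hold the same mice, these p-values measure how alike the difference was across regions and are too small as evidence on genotype. Within a region there was 1 array per genotype and no test. Genes were counted there by a size rule of 2-fold, and the error given is the scanner software's spot error, which covers measurement on the array and no difference between mice. The number of arrays limits the precision throughout. Each region was also set against the mean of the other 5 in a limma fit with genotype as a covariate, with an adjusted p under 0.05 and a log2 difference of at least 1.

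Lists of genes were fixed before the data were examined, 29 in all with 500 entries, of which 41 had no named probe. They covered the IL-18 pathway, neuropeptides, neuropeptide receptors, dense-core granule proteins, energy balance, serotonin and dopamine genes, markers of the hypothalamus, thalamus, striatum, hippocampus, amygdala, cerebral cortex and olfactory bulb, markers of choroid plexus, ependyma, microglia, astrocytes, oligodendrocytes, endothelium with pericytes and red blood cells, pan-neuronal, GABA neuron and glutamate neuron genes, immediate early, circadian clock, glucocorticoid-responsive, interferon-responsive and antigen presentation genes, and genes flanking Il18. Across regions they were tested with camera of limma at its preset correlation of 0.01, and within a region the list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression. There a member counted where it was well above background on at least 1 of the 2 arrays, so a dim array's own reading enters the list's median and counts, though not the genes named with a fold. Lists with at least 3 measured members were used.

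Named genes followed a rule set before the data were examined. Across regions, these were the 12 largest rises and 12 largest falls past the threshold with 1 direction in all 6 regions or, where under 5 passed, the 5 of smallest p, given as values. In the amygdala they were the 12 largest rises and falls on the size rule and every neuropeptide apart by 2-fold, and in each other region the 6 largest rises and falls. The 5 leading genes of each region, up to 4 members per list, Il18, Il18r1, Il18rap, Il18bp and the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty completed it. Of the genes the rule gave for a region other than the amygdala, some are given with values and the remainder as counts. Which ones were given was chosen after their values were seen, and they are not always the largest differences. Members beyond 4 of the microglia, immediate early and Il18-flanking lists were named after their values were seen, because they passed the threshold over the list alone. Other genes outside the rule are said to have been chosen after their values were seen.

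The fits were tested on simulated data with the arrays' own means and noise for 24817 genes. Of 50 genes changed across the regions by a log2 of 0.5, 1, 2 or 4, the fit recovered 27, 41, 48 and 50 (54%, 82%, 96% and 100%). Beside these calls it made 16 false ones among 24617 unchanged genes. The noise of this simulation was changed to limma's moderated variances after a first run had been seen. For a region against the other 5, it recovered 98% of 200 genes changed by a log2 of 2 and called 1 unchanged gene. The list test recovered a list shifted by a log2 of 0.5 and called no other list. Simulated noise was independent between genes and between arrays. The simulations therefore do not test lists of correlated members or differences that regions share. In the fit across regions, the changed genes of every size were planted in the same run. With so many calls the Benjamini-Hochberg cutoff was looser than in the real fit, which called 10. The recovered shares can therefore overstate what the real fit finds.

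The alternatives, whose effects the closing section gives, were scaling by the median, quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, no filter and a stricter filter on dim probes, the mean of a gene's probes, other size rules, other variance models, the deposited ratios, and leaving out each region or array. The mean spot signal that normexp usually takes was not used here and the median spot signal stood in its place. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.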

Results

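The data compare transcripts between KO and WT mice in 6 regions of the mouse brain, with the title of the series pointing to neuropeptides in the amygdala. Each of the 12 arrays held RNA pooled from 5 male mice of 12 weeks, with 1 WT and 1 KO array for each of olfactory bulb, prefrontal cortex, striatum, amygdala, hippocampus and hypothalamus. The 75th percentile of the processed intensity was lowest on the 2 striatum arrays, at 208 for WT and 272 for KO, and reached 768 on the amygdala KO array. Between 60.8% of the spots (striatum WT) and 81.3% (olfactory bulb WT) were well above background. Repeated spots of a probe above background had a median SD of 0.071 to 0.103 in log2. Values below are log2 differences, KO minus WT, unless another quantity is named, and levels are log2 signals relative to the 75th percentile of the array.

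Across genes, the WT and KO arrays of a region were each other's nearest array in 5 of the 6 regions, with Pearson r from 0.986 in the striatum to 0.994 in the hypothalamus. Genes are not independent replicates, and these r describe the arrays alone. The array labelled amygdala WT was nearest to the hypothalamus WT array (r = 0.993), and its r with the amygdala KO array was 0.981. The amygdala KO array was also nearest to a hypothalamus array, that of the KO (r = 0.985), though at a median absolute log2 deviation of 0.27 among bright genes. Among 9653 bright genes, 3 lay 2-fold apart between the array labelled amygdala WT and the hypothalamus WT array, 1 of them named (Snrpd3, a spliceosome protein, named after its value was seen). The log2 difference had a median absolute deviation of 0.097, the smallest of the 66 pairs of arrays, beside an SD of 0.12 that repeated spots gave for such a difference. Between the 2 hypothalamus arrays 11 genes lay 2-fold apart.

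**Figure D1:**
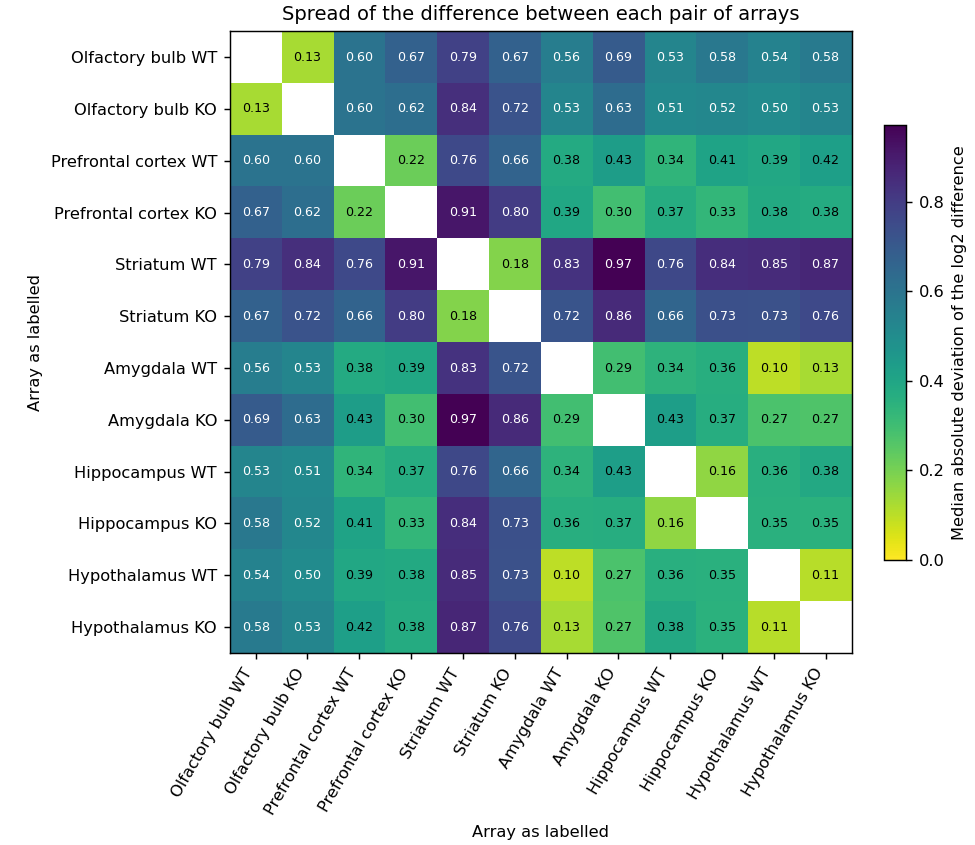
Median absolute deviation of the log2 difference between each pair of the 12 arrays, over 9653 bright genes, with arrays named as labelled on both axes. The pair of the array labelled amygdala WT and hypothalamus WT, at 0.097, is the closest, ahead of hypothalamus WT and KO at 0.11.

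Il18, the targeted gene, was lower on the KO array in every region. The difference was -4.16 in olfactory bulb, -4.26 in prefrontal cortex, -4.38 in striatum, -5.10 in amygdala, -3.73 in hippocampus and -4.52 in hypothalamus. Across the 6 regions Il18 fell by 4.36 (SE 0.16, limma adjusted p = 0.000615). The KO arrays still read above background at this probe, between -4.35 and -3.12 relative to the 75th percentile, and whether the probe lies in the deleted part is not given in the sources used here. Il18r1 and Il18rap, which encode both chains of the IL-18 receptor, were not well above background on any array. Il18bp, a secreted inhibitor of IL-18, differed by -0.12 (SE 0.079, limma adjusted p = 0.372). On these arrays labelled male, Xist and Uty were not above background on any array. Ddx3y, Eif2s3y and Kdm5d, all Y-linked, were above background on all 12, with differences of 0.048, -0.31 and -0.0049 that missed the threshold, the last of which takes the opposite sign under other scalings.

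**Figure D2:**
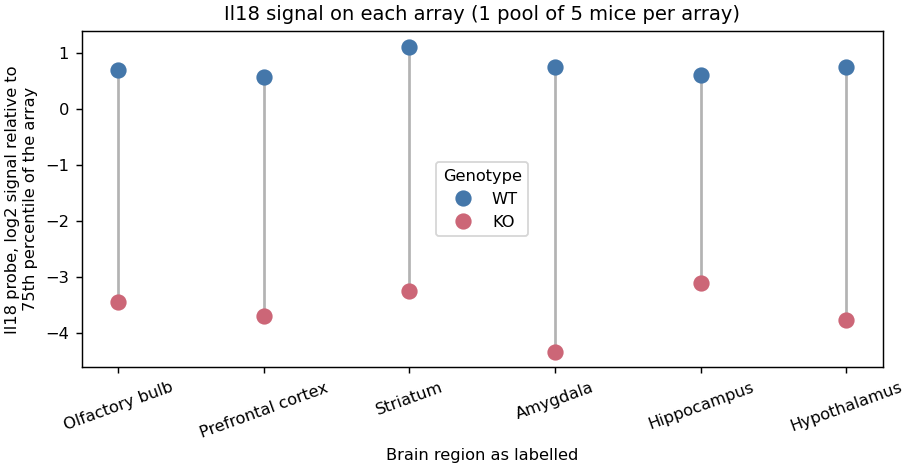
Level of the Il18 probe (log2 signal relative to the 75th percentile of the array) on the WT and KO array of each region, 1 pool of 5 mice per point. The KO arrays lie between -4.35 and -3.12 and the WT arrays between 0.57 and 1.12.

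Across the regions, 3 named genes passed beside Il18 itself, and 2 of them lie close to it. Cryab, a small heat shock chaperone encoded 8 tested genes from Il18, fell by 1.19 (SE 0.093, limma adjusted p = 0.0204) and was lower in 6 of 6 regions. Alg9, a mannosyltransferase of N-glycan assembly 12 genes away, fell by 0.60 (SE 0.053, limma adjusted p = 0.0285), again in 6 of 6 regions. Xxylt1, a xylosyltransferase encoded elsewhere, rose by 0.60 (SE 0.058, limma adjusted p = 0.0455) in 6 of 6. In all, 10 of 24859 genes and transcripts passed, 4 higher and 6 lower in the KO, and 4 of them are named. The count depended on the processing, at 480 with normexp, 1086 among brighter probes and 161 with a trend and robust variance.

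Other genes of small p in this comparison did not pass and are given as values. Among those higher in all 6 regions, Fdx1, an electron donor of mitochondrial steroid synthesis, differed by 0.56 (SE 0.067), Hyou1, a chaperone of the endoplasmic reticulum, by 0.48 (SE 0.057), Rexo2, an oligoribonuclease, by 0.43 (SE 0.049) and Zc3h6 by 0.42 (SE 0.046). The value of Zc3h6 rests on its brightest probe and was -0.030 as the mean of its probes. Among those lower in all 6, Impg2 differed by -1.16 (SE 0.13) and Atm, a kinase of the DNA damage response, by -0.89 (SE 0.12). Their limma adjusted p ran from 0.0771 to 0.0931. Fdx1, Hyou1, Rexo2 and Atm all lie within 51 tested genes of Il18.

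Of the 300 tested genes nearest to Il18, 150 on each side, 2 passed the adjusted threshold, against 1 of 13759 named genes elsewhere (two-sided Fisher's exact test, p = 0.00134). At an unadjusted p under 0.001 the counts were 16 of 300 (5.33%) against 123 of 13759 (0.894%), and Fisher's exact test gave p = 4.4e-08. Fisher's test takes genes as independent, which genes of the same arrays are not. The comparison was also chosen after the results were seen, so both p-values only describe the clustering. Of the list of genes flanking Il18, 29 were measured. Counted over all genes tested, 2 of them fell and none rose, and adjusted over the list alone 5 fell (Cryab, Atm, Alg9, Hspb2 and Dixdc1) and 2 rose (Fdx1 and Rexo2). Hspb2, a small heat shock gene beside Cryab, and Dixdc1 were named after their values were seen, both at -0.26. The median of that list was -0.099, and as a whole it did not pass the list test (camera adjusted p = 0.468). That test looks for a shift in 1 direction, and 13 members were higher and 16 lower. The mixed test of fry of limma, for members changing in either direction, gave an adjusted p of 9.1e-06. That test does not set a list against the other genes. Lists not chosen by position passed it too, such as astrocyte markers (fry mixed adjusted p = 0.00081).

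These across-region p-values are too small as evidence on genotype, since the pools of the 6 regions may come from the same 5 mice per genotype. Leaving out the region labelled amygdala left 1 gene past the threshold, Il18, and no omission of 1 region left Cryab, Alg9 or Xxylt1 past it. At an unadjusted p under 0.05, 5788 genes (23.3%) passed, and 17.0% of genes had 1 direction in all 6 regions, where independent regions would give 3.13%.

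**Figure D3:**
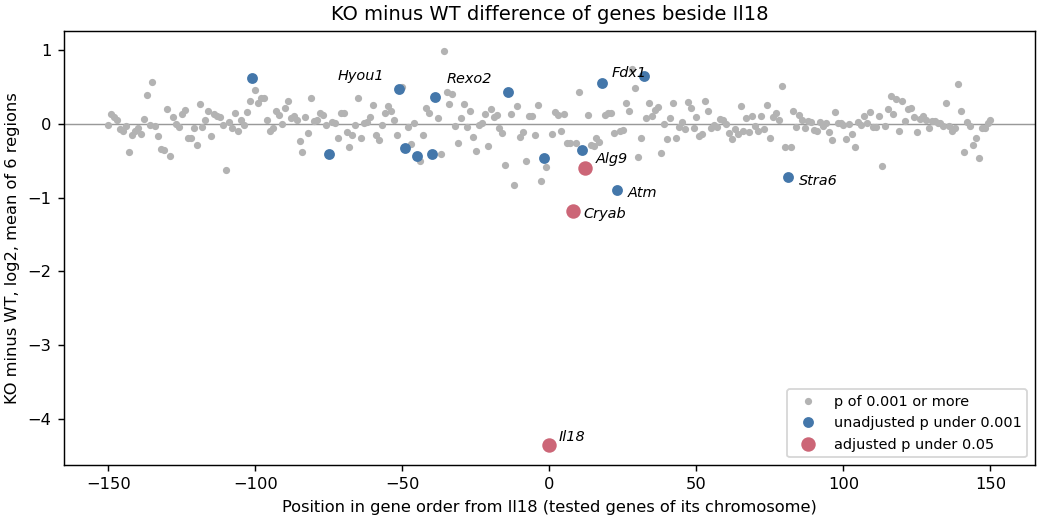
KO minus WT difference (log2, mean of 6 regions) of the 150 tested genes on each side of Il18, in their order along the chromosome. Large red points passed an adjusted p of 0.05 and blue points an unadjusted p of 0.001, with Cryab at -1.19, Alg9 at -0.60 and Fdx1 at 0.56.

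Among the gene lists, microglia markers rose and immediate early genes fell across the regions by camera at its preset correlation, and neither call held with an estimated correlation (p = 0.137 and p = 0.0867, adjusted p = 0.886 for both). Of 16 measured microglia markers, 13 were higher in the KO, with C1qa and C1qb, subunits of complement C1q, at 0.44 (SE 0.069) and 0.38 (SE 0.067), and Siglech, a microglial lectin, at 0.41 (SE 0.12). Adjusted over the list alone, 6 rose (C1qa, C1qb, Siglech, Cx3cr1, C1qc and Ctss) and Laptm5, a lysosomal membrane protein, fell, while 0 passed over all genes tested. The list's median was 0.15 (camera adjusted p = 0.00764, and p = 0.137 with an estimated correlation). The list was also higher on the KO array labelled amygdala, by a median of 0.28 with 16 of 16 members, where the array labelled amygdala WT lay 0.033 from hypothalamus WT in this list. Without the amygdala arrays the call stood, at a camera adjusted p of 0.0434.

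Of 17 immediate early genes, which neurons induce within minutes of activity, 12 were lower in the KO. Egr2 and Nr4a1, both transcription factors, stood at -0.52 (SE 0.097) and -0.47 (SE 0.099), and Fos at -0.45 (SE 0.068). Adjusted over the list alone, 7 fell (Egr2, Nr4a1, Fos, Ccn1, Ier2, Klf4 and Junb) and Homer1, a synaptic scaffold gene, rose, while 0 passed over all genes tested. The list's median was -0.21 (camera adjusted p = 0.00764), and beside the loss with an estimated correlation (p = 0.0867) its call was lost without the hypothalamus arrays (camera adjusted p = 0.0978). Within regions its median was -0.30 in olfactory bulb, -0.32 in prefrontal cortex, -0.25 in striatum, -0.18 in hippocampus and -0.26 in hypothalamus, each below the central 95% of random lists, and 0.0064 on the pair labelled amygdala, within it. Neither list passed the directional test of fry of limma, which called 0 lists, with an adjusted p of 0.0900 for both. In fry's mixed test, of members changing in either direction, the adjusted p were 0.0027 for microglia markers and 0.00024 for immediate early genes. Many other lists passed that mixed test too, among them astrocyte, endothelial and pericyte, glutamate neuron and circadian clock genes, so passing it is not particular to these 2 lists. The same 5 mice per genotype may lie behind all 6 regions here too, so these p-values are too small as evidence on genotype.

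In the amygdala, the 3 largest differences between the 2 arrays were those of neuropeptides of the hypothalamus. Pmch, the precursor of melanin-concentrating hormone, was 202-fold lower on the KO array, a log2 difference of -7.65 (spot error 0.21). Hcrt, the orexin precursor, differed by -7.07, Oxt (oxytocin) by -6.15 and Avp (vasopressin) by -4.57. Agrp, a feeding peptide of the arcuate nucleus, differed by -3.52, and Hdc, the enzyme of histamine synthesis, by -3.99. In the authors' deposited table the log2 ratios in the amygdala were -7.66 for Pmch, -7.08 for Hcrt, -6.16 for Oxt and -4.58 for Avp.

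Of 34 measured neuropeptides in the amygdala, 22 were lower and 12 higher on the KO array, 13 and 2 of them by 2-fold or more, with a median of -0.47. Median scaling gave a median of -0.26, and over the 33 neuropeptides tested across regions the median of WT minus KO was 0.28. Beside those above, Ghrh differed by -2.37, Gnrh1 by -1.99, Gal (galanin) by -1.87, Npb by -1.48, Cartpt by -1.46, Pomc by -1.44 and Trh by -1.30, and Nmu, the remaining 1, was not well above background on the KO array and has no fold here. Qrfp and Ucn (urocortin) were higher on the KO array, by 1.61 and 1.06, at levels below -2 on both arrays. Sst (somatostatin) and Npy, both abundant peptides, were at 5.51 and 1.57 on the WT array and 5.77 and 1.95 on the KO array, and were chosen after their values were seen.

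The array labelled amygdala WT carried the peptides at the levels of the hypothalamus. Pmch stood at 6.02 on it, at 5.92 on hypothalamus WT and 5.93 on hypothalamus KO, and at -1.64 on the amygdala KO array. Oxt stood at 4.70, 4.37, 5.35 and -1.45 in the same order. Over those 33 neuropeptides, the median difference between the array labelled amygdala WT and hypothalamus WT was 0.069.

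**Figure D4:**
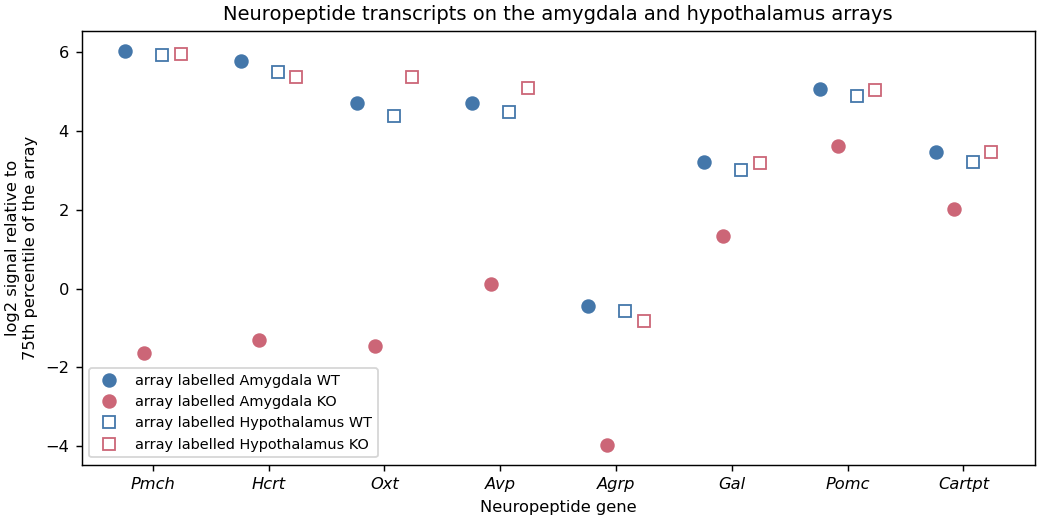
Levels of 8 neuropeptide transcripts (log2 signal relative to the 75th percentile of the array) on the WT and KO arrays labelled amygdala and hypothalamus. The array labelled amygdala WT lies with both hypothalamus arrays, for example at 6.02 for Pmch beside 5.92 and 5.93, and the amygdala KO array lies below, at -1.64.

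Non-peptide genes of the hypothalamus moved the same way between the amygdala arrays. Of 16 measured hypothalamus markers 15 were lower on the KO array, 9 of them by 2-fold, with a median of -1.85, and Asb4 differed by -3.80. The array labelled amygdala WT differed from hypothalamus WT by a median of 0.069 in these markers. Choroid plexus markers, which belong to the epithelium that makes cerebrospinal fluid, were lower in 14 of 14 members with a median of -2.14, and there the 2 WT arrays lay 0.036 apart. Ependymal markers were lower in 6 of 6, with a median of -1.51 and 0.14 between the 2 WT arrays. Amygdala markers were higher on the KO array in 8 of 8 members (median 0.30), cerebral cortex markers in 14 of 16 (0.36), pan-neuronal genes in 10 of 11 (0.23) and glutamate neuron genes in 6 of 8 (0.34). In these lists the array labelled amygdala WT differed from hypothalamus WT by -0.030, 0.014, -0.0047 and 0.025.

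Genes of immune response were lower as well on the KO array labelled amygdala. Of 20 measured interferon-responsive genes 19 were lower (median -0.41), and of 10 antigen presentation genes 8 were lower (median -0.44). The array labelled amygdala WT differed from hypothalamus WT by 0.036 and 0.12 in these lists. Energy balance genes had a median of -0.35 over 16 members, but their WT minus KO median was 0.040 over the 15 tested across regions, so the value depends on which members are counted. Medians were -0.23 for glucocorticoid-responsive genes and -0.23 for myelin genes. The 2 WT arrays differed by 0.053, 0.095 and 0.014 in these 3 lists, the first over the 15 genes. In all, 14 of 29 lists lay outside the central 95% of random lists in the amygdala, and 14 did so in the hypothalamus. The counts were 5, 5, 6 and 8 in olfactory bulb, prefrontal cortex, striatum and hippocampus. Random lists do not keep the correlation between a list's members, so these counts are descriptions.

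By the size rule, 1554 genes and transcripts differed by 2-fold in the amygdala, 118 higher and 1436 lower on the KO array, and 431 of them are named. Of the 1554, 85.1% belonged to the dimmer part of the measured range. The other lowest differences were those of Il18, the receptor Mrgprh (-4.03), the olfactory receptor Olfr545 (-3.89), Cyp2f2 (-3.35) and Myo1e (-3.20). The highest ran from 2.83 for Vmn1r81, a vomeronasal receptor, through Cyp2c23, Gfi1, Olfr830, Kcng3, Foxp4, Olfr476, Chrnb3, Spc24, Cdh4 and Olfr775 to 1.65 for Tmprss7. With 1 array per genotype there was no test. Scaling by the median moved the median of all genes in the amygdala from -0.056 to 0.16 and the share of higher calls from 7.59% to 28.8%. The list medians above are best read against these all-gene medians. Without genes 2-fold apart between the hypothalamus KO and amygdala KO arrays, an alternative added after the data were seen, 742 genes remained.

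The neuropeptide list was also set beside the other regions. The neuropeptide median was -0.47 in the amygdala and 0.014 ± 0.096 (SD, n = 5 regions) in the others, which ran from -0.098 in prefrontal cortex to 0.13 in hypothalamus. The amygdala ranked lowest of 6, for which an exact rank test can give no p below 0.167 one-sided or 0.333 two-sided. The mean of the list was -1.25, below its median, and without peptides that are also energy balance genes the median was -0.24. In the hypothalamus itself, 21 of 35 neuropeptides were higher on the KO array and 14 lower, and Oxt and Avp were at 5.35 and 5.08 there, against 4.37 and 4.46 on the WT array. Across the 6 regions the list did not pass (median -0.13, camera adjusted p = 0.555), nor did neuropeptide receptors (-0.039, adjusted p = 0.666).

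In the prefrontal cortex, 204 genes were higher and 817 lower by 2-fold, and 174 of these 1021 are named. Oprk1, the kappa opioid receptor, differed by -1.96, and Olfr1299, Lrrc18, Mcpt4 and Krt2 fell further, from -2.57 to -1.99. Mme, the peptidase neprilysin, was higher by 2.64 from a dim level of -4.91. Sox3, a transcription factor of neural progenitors, was higher by 2.33, less than Olfr381, C1qtnf3 and Hhip. Neuropeptide receptors had a median of -0.14, glutamate neuron genes -0.19, GABA neuron genes 0.17 and microglia markers 0.16. Under median scaling 294 of 881 calls (33.4%) were higher, against the 204 of 1021 above, and the median of all genes moved from -0.059 to 0.063.

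In the striatum, choroid plexus markers were higher on the KO array in 12 of 13 members, with a median of 1.51. All 8 members higher by 2-fold were not well above background on the WT array, so this median rests on dim WT readings. The members above background on both arrays, named after their values were seen, changed less. Igf2, Clic6, Enpp2 and Folr1 stood at 2.41, 1.15, 2.95 and -1.52 on WT and at 2.56, 1.31, 3.65 and -0.77 on KO. Prlr was lower, at -1.62 on WT and -1.69 on KO. Ttr, which encodes transthyretin, was not well above background on the WT array and stood at 0.050 on the KO array. By 2-fold, 160 genes were higher and 152 lower. Il21r, the interleukin-21 receptor, was higher by 2.69 and Zfp36, which destabilises mRNAs of cytokines, by 2.15, while Capg, an actin-capping protein, differed by -3.11. The same 3 genes averaged -0.29, 0.049 and -0.16 over the other 5 regions. Dense-core granule proteins were higher in 14 of 14 members (median 0.15), while amygdala markers and the IL-18 pathway had medians of -0.20 each. The balance of calls was not stable: 51.3% were higher here, 40.5% with median scaling, 71.6% with no filter and 28.8% (15 of 52) with the stricter filter.

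In the hippocampus, 186 genes were higher and 245 lower by 2-fold, and with the stricter filter 7 of 53 were higher, but at 3-fold 56 of 94 were. Sln, a regulator of the sarcoplasmic calcium pump, was higher by 2.97, and Ski, a repressor of TGF-beta signalling, differed by -1.92. Olfr172, Rassf9, Lipg and Col27a1 fell further, from -2.26 to -1.99. Myelin genes were higher in 13 of 15 members (median 0.24), choroid plexus markers in 13 of 14 (0.69) and ependymal markers in 6 of 6 (0.31). Thalamus markers were lower in 9 of 10 (-0.22) and endothelial and pericyte markers in 15 of 15 (-0.095).

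In the hypothalamus, 90 genes were higher and 153 lower by 2-fold, and with the stricter filter 4 of 29 were higher. Choroid plexus markers were lower in 14 of 14 members with a median of -1.04. Hypothalamus markers were higher in 15 of 19 (median 0.27) and myelin genes in 14 of 15 (0.16). Amygdala markers were lower in 7 of 8 (-0.27) and glutamate neuron genes in 7 of 8 (-0.19). Prg3, an eosinophil granule protein, was higher by 4.28 and Igfals, a carrier of insulin-like growth factors, by 2.80, both from levels below -4 on the WT array. Antigen presentation genes had a median of -0.20, which turned to 0.10 in the brighter genes alone.

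In the olfactory bulb, 79 genes were higher and 158 lower by 2-fold, and with the stricter filter 1 of 15 was higher. The differences included Agr2, a protein disulphide isomerase, at -3.15 and Itga1, an integrin chain, at -2.77. Amh, anti-Müllerian hormone, was higher by 2.79 and Evx1, a homeobox factor, by 3.47. Red blood cell genes were lower in 3 of 3 members (median -0.81) and higher in 2 of 3 in the hypothalamus (0.74). Neuropeptide receptors had a median of -0.13, which was 0.020 in the brighter genes alone. In these 5 regions between 83.2% and 93.7% of the 2-fold calls belonged to the dimmer part of the measured range, and their highest and lowest differences beside Il18 included olfactory receptors in all 5. No test was possible within a region with 1 array per genotype.

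**Figure D5:**
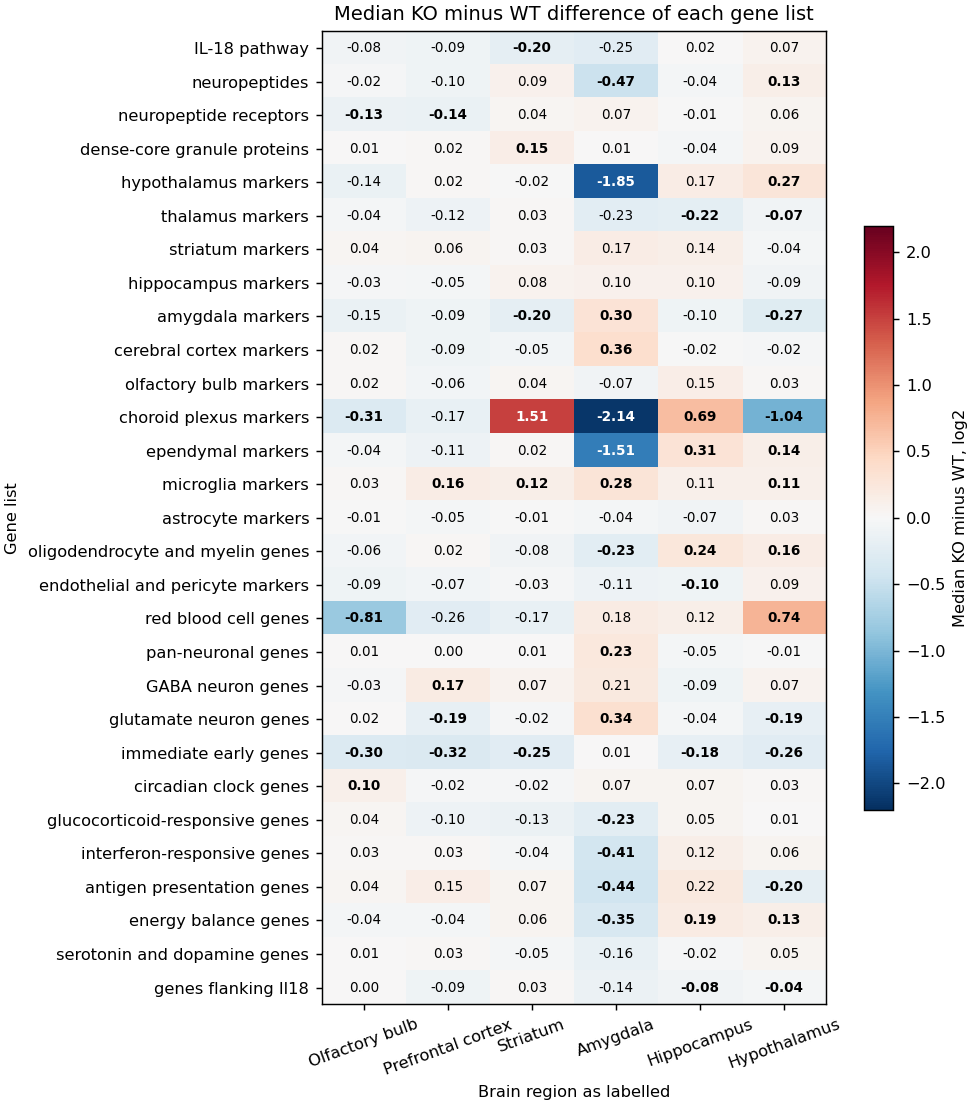
Median KO minus WT difference (log2) of the 29 gene lists in each region, with values outside the central 95% of random lists in bold. Choroid plexus markers range from -2.14 in amygdala to 1.51 in striatum, where most members were not well above background on the WT array. Immediate early genes are below 0 in all regions but the amygdala, at 0.0064.

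The KO minus WT differences of the regions were compared across 24859 genes. Pearson r of the 15 pairs of regions had a median of 0.198 and ran from -0.016 for striatum and amygdala to 0.553 for prefrontal cortex and amygdala. Prefrontal cortex and hippocampus correlated at 0.465, and prefrontal cortex and olfactory bulb at 0.371. All 4 pairs with an r under 0.1 held the striatum, whose arrays were the dimmest. Without the pair labelled amygdala the median r was 0.186, with no filter on dim probes 0.103 and with the stricter filter 0.389. Genes are not independent replicates, so no p is given.

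Each region was also set against the other 5. S100a5 stood 8.28 (SE 0.16) above the mean of the other 5 regions in the olfactory bulb, followed by Doc2g, Cdhr1, Cpa6 and Tbx21, and 1755 genes were higher there. In the striatum 3246 genes were higher, led by Myo1e, Tgm5, Rgs9 (a regulator of dopamine receptor signalling, 6.54, SE 0.20), Itga1 and Nexn. In the hippocampus 1270 were higher, among them Spink8 (5.26, SE 0.14), Ttr, Prdm8, Il20rb and Neurod6, a neuronal transcription factor (4.12, SE 0.39). In the prefrontal cortex 715 were higher, led by Hkdc1, Tcap, Dkkl1, Adra1b and Pmaip1. The limma adjusted p of these named genes were 0.0136 or lower.

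For the amygdala 428 genes were higher, led by Avp, Prl, Trhr, Calcr and Ttr. Of these, Avp stood at 4.69 on the array labelled amygdala WT and at 0.12 on the KO array and Calcr (the calcitonin receptor) at 0.77 and -1.23. Trhr, the receptor of thyrotropin-releasing hormone, was alike on both, at -0.24 and -0.17. In the hypothalamus 458 genes were higher, led by Pmch, Avp (7.01, SE 0.94), Hcrt, Oxt and Prl. The limma adjusted p of the genes named for these regions were 0.0380 or lower. Without the array labelled amygdala WT, in part an alternative added after the data were seen, the counts were 504 in the amygdala and 536 in the hypothalamus. The pools of all regions may come from the same 5 mice per genotype here too, so these p-values describe how alike the arrays were and not how mice vary.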

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

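The tests of the amygdala pattern, of the chromosome segment beside Il18 and of array position were chosen only after the results were seen, and the bounds for other probes and for array position were made stricter after their values were seen.

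Of 44 groups of 6 values examined, 9 held a value far from the other 5, where chance marks about 1 in 20 groups, or 2.2 here. On the pair labelled amygdala, 6 lists stood apart from the other regions. These were hypothalamus markers (-1.85, next -0.14), ependymal markers (-1.51, next -0.11), interferon-responsive genes (-0.41, next -0.041), amygdala markers (0.30, next -0.091), cerebral cortex markers (0.36, next 0.019) and pan-neuronal genes (0.23, next 0.012). Alg9 differed by -0.42 in the hippocampus, less than the -0.60 to -0.69 of the other regions. Il18bp differed by 0.25 in the striatum, where the other regions lay between -0.28 and -0.11. The striatum WT array had a 75th percentile intensity of 208, below the 502 to 636 of the other WT arrays.

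Neuropeptides and hypothalamus markers were far lower on the KO than on the WT array labelled amygdala. The tables argue against a fall of neuropeptides in every region, since the list's median was 0.13 in the hypothalamus, and against an exchange of the amygdala WT and hypothalamus WT samples, since hypothalamus markers differed by 0.27 between the hypothalamus arrays, where an exchange needs 1 or higher. Hypothalamic tissue or RNA on the array labelled amygdala WT may account for the pattern: over 116 bright genes 2-fold apart between the hypothalamus KO and amygdala KO arrays, the slope of amygdala WT minus hypothalamus WT on the same difference between the KO arrays was -0.0177 (SE 0.0194), against 0.929 to 1.03 for the other 4 regions. A slope towards hypothalamus that has amygdala KO on both axes was 0.790 over 1500 genes (median ratio 0.997), but in that construction hypothalamus WT moved towards amygdala by 0.217, so the shared array can raise it. A fall of peptides confined to the KO amygdala is argued against as the whole cause, since it would leave the other genes alone. Over 9653 bright genes, the median absolute deviation was 0.097 between amygdala WT and hypothalamus WT and 0.27 between the KO arrays of these regions. Choroid plexus markers differed by a median of 0.036 between those WT arrays and by 1.04 between the hypothalamus arrays. A further fall of the peptides cannot be told apart, with 1 pooled array per genotype. An exact rank among 6 regions reaches no p below 0.167. Whether tissue or the hypothalamus WT pool itself was on the array was not tested.

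Genes past the threshold across the regions clustered beside Il18. A chromosome segment of another strain, kept around the targeted locus through breeding, is a candidate explanation: the share of called genes was 91.7 times that of genes elsewhere, though it rests on 2 genes against 1, and at an unadjusted p under 0.001 the ratio was 5.97. These ratios restate the clustering. Any cause acting near the locus would give them, so they do not single out a strain segment. Strain variants under single probes were tested on 6 neighbours called by any probe, of which 5 (a share of 0.833, exact binomial 95% interval 0.359 to 0.996) had another probe that went the same way at an unadjusted p under 0.05. The other probe changed far less in some, -0.15 against -1.47 for Vps11, -0.18 against -1.32 for Pcsk7 and -0.039 against -0.97 for Rps25 (named after their values were seen), which variants under probes and the choice of the probe of lowest p both produce, so the 2 cannot be told apart here, and the interval reaches below the bound of 0.75. An effect of losing IL-18 on these genes was not tested and stays open.

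The differences of prefrontal cortex and amygdala correlated at an r of 0.553. A trend with spot brightness is argued against as the whole cause, since r was 0.517 with each region's trend removed. A shift between transcript classes is argued against as the whole cause, since r was 0.406 within RefSeq transcripts and 0.623 within the remaining transcripts. The medians of RefSeq and remaining transcripts were -0.014 and -0.16 in prefrontal cortex, and 0.00079 and -0.18 in amygdala. Both gaps were smaller than the one set beforehand for this cause. The ratio of 0.734 within RefSeq transcripts lay just under the bound of 0.75 set beforehand, so a part played by class cannot be told apart. Array position, which follows genotype on every slide, cannot be told apart, because the 4 pairs of regions with r under 0.1 all involve the striatum slide. The amygdala difference also uses the array labelled amygdala WT, at a median absolute deviation of 0.097 from hypothalamus WT and 0.29 from amygdala KO. It can therefore hold a difference of tissue, whose part in r was not tested. A shared effect of genotype stays open but cannot be told apart from these.

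The count of 10 genes past the threshold across the regions was set against other assignments of the labels. Of 32 ways to turn the genotype labels within regions 1, the real one, gave as many, and the highest other gave 0 genes. That is the smallest share 32 turns can give, and chance turning is argued against at that level only. The 10 genes include Il18, the targeted gene. Such turns treat the regions as independent, and where all regions share the same 5 mice per genotype they do not exclude a fixed difference between the 2 sets of mice. Nor do they exclude an effect of array position, which follows genotype on every slide. Of the 462 possible splits of the 12 arrays 10 allow no estimate, and of 100 drawn from those left 1, the real split, gave as many, while the highest other gave 1 gene. Of these others 38 part 2 of the 6 region pairs, 54 part 4 and 7 part 6, and pairs that are not parted add nothing to a fit with region as a block. Most of them had little chance to reach the real count, so this count of splits adds no evidence on chance beyond the turns within regions.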

How the results depend on the processing

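Alternatives without the 150 neighbours of Il18, without arrays labelled amygdala (outside the planned omission of each region or array), without genes apart between hypothalamus KO and amygdala KO, and with each probe tested by itself were added after the data were seen, while all others were fixed before the data were examined. Of the recomputed values of the main results 134 stayed the same by their rule and 71 moved. Il18 kept its direction and its side of the threshold in every alternative that gave a value. It gave none under the stricter filter, which takes the mean over WT and KO arrays. The low KO readings brought that mean under the cut, though the WT levels were 0.57 to 1.12. Slide and region are the same block, so the slide alternative was not run. The cause of the changes below was not tested, except where fewer arrays, a different size rule or a different set of genes makes it.

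Across the regions the count of 10 genes became 17 with quantile normalization, 480 with normexp, 1086 among probes brighter than the median, 2 without region as a block, 161 with a trend and robust variance, 5788 at an unadjusted p under 0.05 and 5 without the neighbours of Il18. Leaving out 1 region gave 1 to 5 genes (3 without olfactory bulb, 2 without prefrontal cortex, 5 without striatum, and 1 without each of amygdala, hippocampus and hypothalamus). The 2 lists became 0 with an estimated correlation, 0 with fry's directional test and 1 to 3 when 1 region was left out. Choroid plexus markers were called lower without striatum (camera adjusted p = 0.0089).

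Counts of 2-fold genes are given in the order olfactory bulb, prefrontal cortex, striatum, amygdala, hippocampus and hypothalamus. They were 54, 162, 132, 275, 95 and 44 with normexp, 1258, 2581, 2191, 3229, 1666 and 1232 with no filter, and 15, 172, 52, 231, 53 and 29 with the stricter filter. They were 1050, 3011, 1253, 4284, 1858 and 865 at 1.5-fold and 95, 170, 99, 374, 94 and 80 at 3-fold. The amygdala count was 742 without genes apart between hypothalamus KO and amygdala KO. The deposited ratios gave 189, 708, 230, 1167, 354 and 194, within 1.5 times of the main counts. The share of higher calls moved to 30.2% (quantile) in prefrontal cortex and from 51.3% to 40.9% (normexp), 71.6% (no filter) and 28.8% (stricter filter) in striatum. The stricter filter also moved it from 33.3% to 6.67% in olfactory bulb, from 43.2% to 13.2% in hippocampus (59.6% at 3-fold) and from 37.0% to 13.8% in hypothalamus. Most 2-fold calls came from dim spots, where signal over background limits what can be read.

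Counts of genes higher in a region became 874, 349, 1596, 211, 407 and 240 with normexp and 532, 401, 1406, 215, 324 and 206 with the stricter filter, in the same order. The striatum had 7272 with no filter and the amygdala 936 with median scaling. Lists outside the central range became 3 in prefrontal cortex with quantile normalization and 3 with the stricter filter, which gave 9 in the hypothalamus. The neuropeptide median in the amygdala was -0.26 with median scaling, -0.32 with normexp, -0.28 with no filter, -0.61 with the stricter filter, -0.24 without energy balance peptides and -1.25 as a mean, lowest of the 6 regions each time. The median r between regions was 0.389 with the stricter filter and 0.103 with no filter.

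Reversed values were Kdm5d at 0.052 (median scaling), 0.028 (quantile) and 0.020 (normexp), Zc3h6 at -0.030 (mean of probes), thalamus markers in the hypothalamus at 0.038 (normexp) and 0.12 (stricter filter), neuropeptide receptors in the olfactory bulb at 0.020 and antigen presentation genes in the hypothalamus at 0.10 (both stricter filter). Of the values of single genes and lists, 831 stayed the same, 191 moved, 30 lost and 13 gained the threshold, and 8 reversed.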

Other observations

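No tests are weighed in this part, and the genes named in it are the members of fixed lists with the largest differences. Adjusted over the list alone, members of 6 further lists passed across the regions, while 0 did so over all genes tested. Ptprn, a membrane protein of dense-core granules, was higher by 0.39, Nr1d1, a repressor of the circadian clock, by 0.27 and Mog, a myelin glycoprotein, by 0.45, each in 6 of 6 regions. Sox9, a transcription factor of astrocytes, differed by -0.30 in 6 of 6. As lists, none of these passed camera, with medians of 0.050 for dense-core granule proteins (adjusted p = 0.468), 0.027 for clock genes (0.563), 0.016 for myelin genes (0.707) and 0.016 for astrocyte markers (0.666), whose mean of -0.047 and direction in the test were of opposite sign. In the interferon-responsive list (median -0.077, adjusted p = 0.414) Stat2, a transducer of interferon signals, differed by -0.30 and passed over the list alone, and in the thalamus list (-0.095, adjusted p = 0.280) Lef1 and Ramp3 did, at -0.31 and -0.18. The IL-18 pathway list, with 1 of 17 members past the threshold, Il18 itself, had a median of -0.12 (adjusted p = 0.280).

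No member of the lists that follow passed. Their medians, with camera's adjusted p, were -0.20 (0.468) for hypothalamus, 0.070 (0.631) for striatum, -0.054 (0.666) for amygdala, 0.042 (0.707) for cerebral cortex, 0.058 (0.666) for olfactory bulb, -0.26 (0.414) for choroid plexus, -0.20 (0.586) for ependymal and -0.049 (0.468) for endothelial and pericyte markers. They were -0.034 (0.666) for red blood cell, 0.024 (0.666) for pan-neuronal, 0.051 (0.468) for GABA neuron, -0.063 (0.666) for glutamate neuron, -0.032 (0.468) for glucocorticoid-responsive, -0.050 (0.934) for energy balance and -0.056 (0.666) for serotonin and dopamine genes. For hippocampus markers the median was -0.041 (0.843) and the mean 0.040, and for antigen presentation genes the median was 0.024 (0.934) and the mean -0.024, with camera pointing lower in both. All lists across regions share the limit that the pools may hold the same mice.

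Transcripts with no RefSeq name were lower than RefSeq transcripts on the KO arrays in 5 of the 6 regions. Their median difference was -0.16 in prefrontal cortex and -0.18 in amygdala, against -0.014 and 0.00079 for RefSeq transcripts, and 0.084 against -0.0084 in striatum. The mean r over the 15 pairs of regions was 0.217, the highest of 32 assignments of genotype labels within regions, the next being 0.194.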
